A study of Oryza sativa with 12 samples.

How the data were processed

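Leaf messenger RNA was measured in 12 libraries of rice cultivar Quan Youde Zhan, 3 in each of the groups CK, Cd, SeNP and CdSeNP. Per the labels, poly(A) RNA was made into Illumina TruSeq libraries, and all libraries carry the same batch label. The submitters' processing notes name HISAT2, StringTie 2.2.1, DESeq2 1.34.0 and the genome build IRGSP-1.0. The trimming tool, the counting rule, its strandedness and the design of the test are not given in the sources used here.

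The deposited tables, one for each of 6 pairs of groups, hold raw read counts per gene made by the authors, unscaled. The FPKM values are those of the authors, scaled to gene length and library size. The log2 fold changes are those of the authors, for the first-named group against the second. The p-values, raw and adjusted, are also from the authors' DESeq2 columns. Every listed gene had an adjusted p under 0.05 and an absolute log2 change of at least 1, so the tables hold the genes the authors called. The tables together list 4170 genes, of which 4007 carry AGIS_Os identifiers and 163 are loci outside that annotation. For 1773 genes the tables together give all 12 libraries, and no gene had conflicting values between tables. Of the 4170 genes, 1046 have no description.

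Library totals, recovered from the ratio of counts to FPKM, were 20977432 to 27772342 counts. Each count carries at least the error of counting, and replicates spread further, with a chi-square per degree of freedom of 7.32 to 27.2 between replicate pairs. The number of genes tested by the authors, recovered from raw and adjusted p, was 21522 to 22079 per comparison. At least 6330 genes had an adjusted p under 0.05 between Cd and CK, 2480 between SeNP and CK, 8857 between CdSeNP and CK, 5297 between CdSeNP and Cd, 7261 between CdSeNP and SeNP and 6864 between SeNP and Cd, whatever the size of the change. The authors' size factors were recovered from counts and fold changes of genes with at least 150 counts. Against scaling by library totals they shifted all log2 changes by -0.187 between Cd and CK and by 0.146 between SeNP and Cd, and by less than 0.1 elsewhere. Changes are given relative to the authors' scaling.

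The main results are the genes called by the authors, counted per direction. Listed genes were fitted again with DESeq2 1.42.0 (for log2 changes and standard errors) and with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3), using the recovered size factors. The refits tested the listed genes alone, so they rate these genes and find no others. The interaction of Cd and SeNP was tested by edgeR in the 1773 genes with 12 libraries, with Benjamini-Hochberg (BH) adjustment. Those genes were listed because groups differed, so its count is no share of all genes. Overlaps of lists were set against the product of list sizes divided by the genes tested, and against simulated libraries. Simulated genes were drawn independently of each other, so these libraries hold no shift shared by many genes of a library.

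The groups, tests and 33 gene lists, matched by words in gene names and descriptions, were fixed before the data were examined. Of the alternatives, edgeR refits and library totals throughout, DESeq2 refits of overlaps and of the interaction, and leaving out replicates in list tests were chosen after the data were seen. Simulated libraries were planned for overlaps, and their form for genes shared by all 3 treatments was chosen then. The lists cover metals and iron, glutathione and redox enzymes, defence, transcription factors, hormones, cell wall, cell cycle, nutrients, photosynthesis, senescence and markers of other tissues. For lists with at least 5 called members, called members higher and lower were compared with the other called genes by Fisher's exact test, two-sided, with BH over 112 tests, of which 25 had an adjusted p under 0.05. A count adjusted over the list alone could not be formed, because p-values of uncalled members were not used here, and for the same reason a list count of 0 refers to the authors' DESeq2 calls alone. List members in no table are not counted among those that did not pass. Some matches are loose: a high mobility group gene (AGIS_Os02g013790) is in the WRKY list, a peroxiredoxin (AGIS_Os02g008510) and an ascorbate peroxidase (AGIS_Os04g012220) are among class III peroxidases, 6 peroxidases such as AGIS_Os07g043560 are outside the class III list, and GSTX1 (AGIS_Os01g063400) is in both the glutathione S-transferase and the auxin response lists. Genes were named by a fixed rule. With a description, a mean of at least 5 FPKM in the higher group and no overlap between replicates, the 6 largest changes per direction were taken, with up to 4 members of each list. Names follow the deposited descriptions, some of which come from relatives in other species. Several genes can carry the same description, so a name can stand for a related gene.

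Coordinates are those of the deposited tables. The notes name IRGSP-1.0, but 88.8% of listed genes lay within a gene of the assembly ASM3414082v1 at the given place (22.5% after a shift of 1 Mb), so the build of the coordinates is taken to be the latter. Histones, metallothionein 4 copies and trehalose-phosphate synthase 10 copies are closely related families between which reads can be shared, so single members are uncertain, and genes that overlap another gene on the other strand are uncertain because strandedness is not given. Fits were tested on simulated data, where 59% to 91% of genes changed by 1 on the log2 scale were recovered by p-value and direction. That recovery did not require an absolute log2 change of at least 1, and only genes above a minimum expected count were changed. Alternatives were a stricter adjusted p (0.01), an absolute log2 change of at least 2, a minimum of 1 FPKM, edgeR and DESeq2 refits, library totals, all 12 libraries in the fit, replicate number as a block, and leaving out each replicate. Not all were run for every result: list tests had the 3 thresholds, the edgeR refit, library totals and leaving out replicates, overlaps had no FPKM minimum and no fit of all 12 libraries, and the interaction had library totals, the DESeq2 refit, the block and leaving out replicates. Ranges cover the alternatives run. TMM scaling and filters on all expressed genes were not analysed here, since the listed genes do not give the whole library. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.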

Results

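Messenger RNA of whole leaves of rice (cultivar Quan Youde Zhan) was sequenced in 12 libraries, 3 from each of 4 groups. The plants grew in nutrient solution and were treated from an age of 3 weeks. The solution held no addition (CK), 10 mg/L hydrated cadmium chloride (Cd), 3 mg/L selenium nanoparticles (SeNP), or both together (CdSeNP). Leaves were taken at the 6-leaf stage, at 1.5 months. The library totals recovered from the deposited tables were 26063264 to 27772342 counts in CK, 20977432 to 26563303 in Cd, 23018774 to 25888098 in SeNP and 24431978 to 26840441 in CdSeNP. Each deposited table lists the genes that the authors called between a pair of groups, so "did not pass" below refers to genes whose counts another of the 6 tables gives. Levels are mean FPKM ± SD (n = 3) and log2 changes come from a DESeq2 refit of the listed genes, ± SE. No label says that the libraries of a group came from separate plants, so p-values of single genes measure only the spread between these samples. Fisher's exact tests of lists count called genes and treat them as independent, so their p-values measure no spread between samples. Genes of a list can change together, and such p-values can then be too small.

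The 4 groups form a crossed design of Cd and SeNP, and 6 pairs of groups were compared. The authors' deposited tables (DESeq2) listed 1468 genes between Cd and CK, of which 1038 were higher and 430 lower with Cd. Scaling by library totals in place of the authors' size factors left 278 of the 430 lower genes. SeNP alone changed fewer genes: 77 were higher and 458 lower than in CK. With both additions, 839 genes were higher and 1600 lower than in CK. When SeNP was added to Cd, 126 genes were higher and 1333 lower than with Cd alone. When Cd was added to SeNP, 962 were higher and 969 lower, and the lower genes went from 969 to 532 without SeNP replicate 2 and to 573 without CdSeNP replicate 2. Between SeNP and Cd, 340 genes were higher and 1511 lower in SeNP, and 210 of the higher ones were left with library totals.

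**Figure D1:**
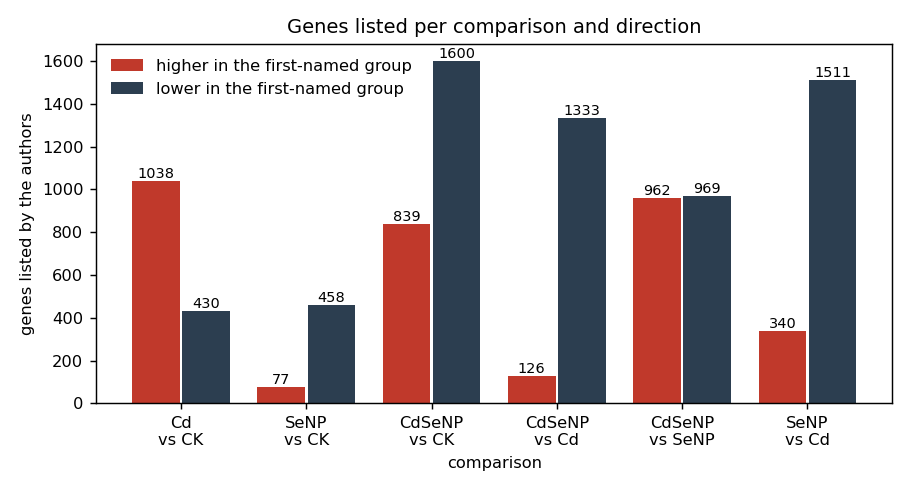
Number of genes (vertical axis) that the authors' tables list as higher or lower in each of the 6 comparisons (bars by direction, first-named group against the second). Cd raised 1038 genes against CK, and adding SeNP to Cd lowered 1333.

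The comparison of Cd with CK asked how leaves responded to Cd alone. Genes of metal handling were among those that rose most. IRO2 (AGIS_Os01g063630, chromosome 1, 42623480 to 42630444), a factor of the iron-deficiency response, stood at 28.5 ± 2.71 FPKM in Cd and 0.269 ± 0.0225 in CK, a log2 change of 6.54 ± 0.25. YSL2 (AGIS_Os02g038710, chromosome 2, 26656733 to 26661316), a transporter of metal-nicotianamine complexes, reached 62.4 ± 4.77 FPKM in Cd and 1.57 ± 0.102 in CK (5.13 ± 0.20). Nramp1 (AGIS_Os07g013740, chromosome 7, 9047201 to 9052060), a transporter of iron that also carries Cd, reached 47.0 ± 4.28 FPKM in Cd and 1.51 ± 0.0980 in CK (4.78 ± 0.22). Among metal transporters, of 12 with counts, 7 rose, 2 fell and 3 did not pass. ZIP1 (AGIS_Os01g065310) rose by 3.33 ± 0.26 on the log2 scale. VIT2 (AGIS_Os09g029830), which moves iron into the vacuole, changed by -2.79 ± 0.27. Of the iron homeostasis genes, 13 had counts, of which 8 rose, 3 fell and 2 did not pass. IRO3 (AGIS_Os03g023360) rose by 1.88 ± 0.21 and the ferric reductase FRO1 (AGIS_Os04g043070) by 1.85 ± 0.24. Metallothioneins, small proteins that bind metals, formed an abundant group. Of 8 members of that list with counts, 7 rose and 1 fell. MT4A (AGIS_Os12g035060) reached 2649 ± 353 FPKM in Cd and 175 ± 5.40 in CK and MT4C (AGIS_Os12g035090, chromosome 12, 24205297 to 24205948) reached 1067 ± 233 FPKM in Cd and 16.0 ± 2.85 in CK. MT4B (AGIS_Os12g035080) rose by 5.52 ± 0.30. These copies are closely related neighbours between which reads can be shared, so single copies are uncertain. Of the genes described as trehalose-phosphate synthase 10, AGIS_Os05g002810 reached 91.9 ± 8.33 FPKM in Cd and 0.522 ± 0.158 in CK (7.27 ± 0.33), with the same limit. The direction of these lists did not pass a test against the other called genes (Fisher's exact test, BH p = 1.00 for metal transporters, 0.787 for metallothioneins and 1.00 for iron genes). In the authors' deposited table (DESeq2) the largest adjusted p of these genes was 4.91e-21, for FRO1 with a log2 change of 1.85.

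Called pathogenesis-related and diterpenoid genes were mostly higher with Cd, and ERF and DREB factors were lower. Among pathogenesis-related proteins, of 56 with counts, 29 rose, 4 fell and 23 did not pass. PR1 (AGIS_Os01g024220) reached 105 ± 14.3 FPKM in Cd and 13.2 ± 2.14 in CK (2.80 ± 0.23), and a thaumatin-like gene (AGIS_Os12g040040) reached 237 ± 34.5 FPKM in Cd and 39.9 ± 7.05 in CK. In diterpenoid phytoalexin synthesis, which makes antimicrobial compounds of rice, of 22 with counts, 15 rose, 0 fell and 7 did not pass. A gene described as an ent-cassadiene hydroxylase (AGIS_Os04g023660) rose by 3.65 ± 0.31 and one described as a momilactone A synthase (AGIS_Os07g042470) by 1.67 ± 0.22. Other genes carry the same descriptions (AGIS_Os02g032060 and AGIS_Os07g042440). Of the WRKY factors, 25 had counts, of which 13 rose, 4 fell and 8 did not pass. A gene described as WRKY45-1 (AGIS_Os03g019350) rose by 1.45 ± 0.26, while WRKY71 (AGIS_Os02g007540) changed by -1.31 ± 0.21. Another gene, AGIS_Os05g022080, carries the same WRKY45-1 description. None of the ERF and DREB factors rose, and of 16 with counts 14 fell and 2 did not pass. ERF109 (AGIS_Os08g034130, chromosome 8, 23493609 to 23494730) fell from 13.9 ± 1.22 to 0.895 ± 0.144 FPKM. The cold-responsive DREB1B (AGIS_Os09g039870) fell from 19.9 ± 4.39 to 2.56 ± 0.836 FPKM, and DREB1A (AGIS_Os09g039890) and DREB1G (AGIS_Os02g040840) changed by -3.05 ± 0.25 and -3.04 ± 0.31. In jasmonate synthesis and signalling, of 14 with counts, 5 rose, 7 fell and 2 did not pass. The repressors TIFY11e (AGIS_Os10g020330) and TIFY11b (AGIS_Os03g007060) changed by -2.97 ± 0.34 and -2.42 ± 0.24, and CYP94C1 (AGIS_Os11g004370), which breaks down jasmonate, by -3.09 ± 0.30. FLZ14 (AGIS_Os03g007240) changed by -3.33 ± 0.28. The direction of ERF and DREB factors differed from that of the other called genes (Fisher's exact test, two-sided, BH p = 1.65e-06, 14 members lower), as did that of diterpenoid genes (BH p = 0.0400, 15 higher). Pathogenesis-related proteins (BH p = 0.123) and WRKY factors (1.00) did not pass that test (Fisher's exact test). The diterpenoid test did not pass without CK replicate 1 (0.0601), CK replicate 3 (0.0655), Cd replicate 1 (0.0636) or Cd replicate 3 (0.0882), nor with library totals, a minimum of 1 FPKM, an adjusted p under 0.01 or an absolute log2 change of at least 2, and its BH p over the alternatives run ranged from 0.0391 to 0.806. For these genes the largest adjusted p in the authors' deposited table (DESeq2) was 1.79e-11, for WRKY45-1 with a log2 change of 1.45.

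Cell cycle and chromatin genes rose together with Cd: of 53 with counts, 48 rose, 1 fell and 4 did not pass. A histone H3.1 gene (AGIS_Os05g031790, chromosome 5, 21606215 to 21606975) stood at 34.0 ± 18.2 FPKM in Cd and 6.34 ± 4.33 in CK, and a histone H4 gene (AGIS_Os02g041330) rose by 2.15 ± 0.42. The median member over 50 genes stood at 3.02 ± 1.32 FPKM in Cd and 1.05 ± 0.231 in CK, and the Cd libraries spread from 4.32 in replicate 1 to 1.68 in replicate 3. Their direction differed from that of other called genes (Fisher's exact test, BH p = 2.45e-05, 48 members higher). Without Cd replicate 1, 18 were higher and 1 lower (Fisher's exact test, BH p = 0.0841; range over alternatives 2.74e-05 to 0.806, highest with an absolute log2 change of at least 2), and without CK replicate 1 or CK replicate 2, 29 were higher. Among markers of other tissues (root, meristem, flower), of 6 with counts, 4 rose, 1 fell and 1 did not pass. A gene described as the growth-regulating factor GRF12 (AGIS_Os10g024970), 1 of these markers, rose by 1.92 ± 0.29. Of the glutathione S-transferases, which join toxic compounds to glutathione, 24 had counts, of which 18 rose, 1 fell and 5 did not pass. GSTU6 (AGIS_Os10g031540) reached 18.8 ± 1.15 FPKM in Cd and 2.55 ± 0.254 in CK. The genes matched as ROS scavenging enzymes, which include the copper chaperone CCS, moved the other way, and all 4 with counts fell. The plastid Cu/Zn superoxide dismutase (AGIS_Os08g041700) fell from 206 ± 17.3 to 82.8 ± 10.9 FPKM, and its copper chaperone CCS (AGIS_Os04g042620) changed by -1.40 ± 0.19. Among class III peroxidases, of 29 with counts, 5 rose, 3 fell and 21 did not pass, and peroxidase 47 (AGIS_Os08g001090) rose by 1.91 ± 0.24. In phenylpropanoid and lignin synthesis, of 26 with counts, 8 rose, 3 fell and 15 did not pass, with laccase-6 (AGIS_Os01g055430) up by 2.59 ± 0.26. In cell wall remodelling, of 32 with counts, 3 rose, 5 fell and 24 did not pass, and without Cd replicate 1 the counts were 2 and 3 (3 and 3 with library totals). XTH24 (AGIS_Os04g045210), a xyloglucan-modifying enzyme, changed by -2.35 ± 0.24. Of the ABC transporters, 23 had counts, of which 11 rose, 1 fell and 11 did not pass, and ABCG43 (AGIS_Os07g029860) rose by 1.87 ± 0.19. Of the cytochrome P450 genes, 56 had counts, of which 36 rose, 8 fell and 12 did not pass. Apart from the cell cycle, no list in this paragraph passed the test of direction (Fisher's exact test, lowest BH p = 0.0806, glutathione S-transferases). The adjusted p of the genes named here was at most 0.00827 in the authors' deposited table (DESeq2), for histone H3.1 with a log2 change of 2.21.

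**Figure D2:**
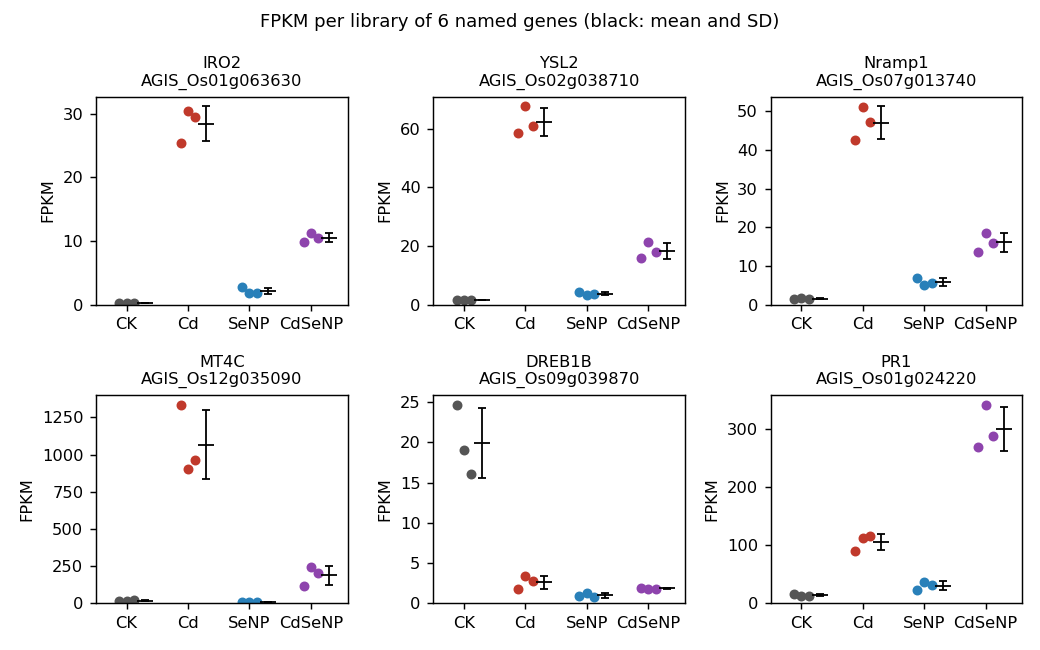
FPKM of 6 genes (vertical axes) in the 4 groups (points, single libraries; lines, mean and SD of 3). IRO2, YSL2, Nramp1 and MT4C were highest in Cd and lower in CdSeNP, PR1 was highest in CdSeNP, and DREB1B was lower than CK in all 3 treatments.

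The comparison of SeNP with CK asked what selenium nanoparticles did to leaves without Cd. Of the called genes of any kind, 14.4% were higher. None of the ERF and DREB factors rose, and all 18 with counts fell. ERF109 (AGIS_Os08g034130) fell from 13.9 ± 1.22 to 0.437 ± 0.0939 FPKM (-5.04 ± 0.32), and DREB1B (AGIS_Os09g039870) from 19.9 ± 4.39 to 0.940 ± 0.272 (-4.47 ± 0.31). DREB1C (AGIS_Os06g002540) and DREB1G changed by -3.60 ± 0.27 and -3.56 ± 0.32. All 18 WRKY factors called were lower, of 29 with counts. WRKY71 fell from 38.7 ± 1.82 to 8.80 ± 1.12 FPKM, and WRKY24 (AGIS_Os01g053440) and WRKY76 (AGIS_Os09g031600) changed by -2.03 ± 0.20 and -1.93 ± 0.19. In jasmonate synthesis and signalling, of 15 with counts, 2 rose, 7 fell and 6 did not pass, with TIFY11e at -3.34 ± 0.31, TIFY11b at -2.45 ± 0.18 and CYP94C1 at -3.14 ± 0.22. Among ABA, LEA and dehydrin proteins, which act in the response to water loss, of 13 with counts, 0 rose, 10 fell and 3 did not pass. An ABA 8'-hydroxylase (AGIS_Os02g042820), which breaks down ABA, changed by -2.18 ± 0.18 and Rab16C (AGIS_Os11g022250) by -1.89 ± 0.24. Of 14 NAC factors with counts, 6 fell and none rose, and NAC2 (AGIS_Os03g052370) changed by -1.91 ± 0.14. An ALP1-like gene (AGIS_Os01g007870) fell from 35.9 ± 4.98 to 1.83 ± 0.367 FPKM, and the kinase gene MAPKKK17 (AGIS_Os01g043200) changed by -3.46 ± 0.32. Among pathogenesis-related proteins, of 53 with counts, 1 rose, 11 fell and 41 did not pass, and with library totals or without SeNP replicate 3 the counts were 1 and 7. A glucanase gene (AGIS_Os01g062680) changed by -1.55 ± 0.26 and thaumatin-like protein 1 (AGIS_Os10g004200) by -1.97 ± 0.33. In the authors' deposited table (DESeq2) the largest adjusted p of these genes was 1.87e-10, for thaumatin-like protein 1 with a log2 change of -1.97.

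Of the genes that rose with SeNP, Nramp1 went from 1.51 ± 0.0980 to 5.83 ± 0.922 FPKM (1.91 ± 0.23). Of the metal transporters with counts, 2 rose and none fell, and 4 of 11 iron homeostasis genes rose. AARE (AGIS_Os04g041640), an enzyme that removes acylated amino acids from peptides, rose by 1.69 ± 0.15, the senescence-linked protease gene SAG39 (AGIS_Os03g046970) by 1.61 ± 0.21, and glycolate oxidase 1 (AGIS_Os08g008560) by 1.84 ± 0.29. A crooked neck-like gene (AGIS_Os10g013610) rose by 2.24 ± 0.23. MT4C changed by -1.26 ± 0.30. Of the cell cycle and chromatin genes, 53 had counts, of which 0 rose, 23 fell and 30 did not pass, and 15 were lower without CK replicate 1 or SeNP replicate 2. A histone H3.1 gene (AGIS_Os05g031790) changed by -3.11 ± 0.58 and histone H2A.5 (AGIS_Os03g014970) by -2.55 ± 0.42. Of the phenylpropanoid and lignin genes, 30 had counts, of which 2 rose, 9 fell and 19 did not pass. Without CK replicate 1 those counts were 1 and 5, and without CK replicate 2, SeNP replicate 1 or SeNP replicate 3, or with library totals, they were 1 and 6. Among class III peroxidases, of 26 with counts, 0 rose, 6 fell and 20 did not pass, and 3 fell without CK replicate 1, CK replicate 2, SeNP replicate 1 or SeNP replicate 2. The adjusted p of the genes named here was at most 9.45e-04 in the authors' deposited table (DESeq2), for histone H3.1 with a log2 change of -3.11. No list differed in direction from the other called genes in this comparison (Fisher's exact test, lowest BH p = 0.0536, cytochrome P450, 5 higher and 6 lower). With 14.4% of called genes higher, the test had little room for wholly lower lists. For 18 ERF and DREB factors lower and 0 higher, its p before adjustment was 0.0905 (Fisher's exact test), so it decides little about them.

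The comparison of CdSeNP with CK asked how leaves with both additions stood against untreated leaves. Most of the called metal-handling genes were higher in CdSeNP. IRO2 stood at 10.5 ± 0.744 FPKM in CdSeNP and 0.269 ± 0.0225 in CK, a log2 change of 5.19 ± 0.22. YSL2 reached 18.4 ± 2.71 FPKM (3.45 ± 0.20) and Nramp1 16.1 ± 2.53 (3.32 ± 0.21). Among metal transporters, all 15 with counts passed, 12 of them higher and 3 lower. ZIP2 (AGIS_Os03g026300), a zinc transporter, reached 51.3 ± 2.83 FPKM in CdSeNP and 9.16 ± 0.465 in CK, and VIT2 changed by -2.70 ± 0.26. Of the iron homeostasis genes, all 13 with counts passed, 10 of them higher and 3 lower. NAAT1 (AGIS_Os02g018220), an enzyme of mugineic acid synthesis, reached 196 ± 5.43 FPKM in CdSeNP and 45.4 ± 5.54 in CK. Of the metallothioneins with counts, 6 rose and none fell. MT4A stood at 1223 ± 179.7 FPKM, MT4C at 186 ± 63.1, and MT1B (AGIS_Os03g015680) rose by 1.23 ± 0.24. The direction of metal transporters (BH p = 0.00284, 12 higher), metallothioneins (BH p = 0.0102, 6 higher) and iron genes (BH p = 0.0124, 10 higher) differed from that of other called genes (Fisher's exact test). The iron test did not pass without CK replicate 2 (9 higher, 3 lower, Fisher's exact test, BH p = 0.0522), and its range over alternatives was 0.00443 to 0.0522. In the authors' deposited table (DESeq2) the largest adjusted p of these genes was 3.02e-12, for MT1B with a log2 change of 1.23.

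Called diterpenoid genes and glutathione S-transferases were mostly higher in CdSeNP, and class III peroxidases mostly lower. Diterpenoid phytoalexin genes were mostly higher, and of 26 with counts, 20 rose, 4 fell and 2 did not pass. The gene described as an ent-cassadiene hydroxylase (AGIS_Os04g023660) reached 20.3 ± 0.299 FPKM (4.98 ± 0.25). PR1 reached 299 ± 37.8 FPKM (4.40 ± 0.20) and the thaumatin-like gene (AGIS_Os12g040040) 548 ± 33.5 (3.68 ± 0.19), although more pathogenesis-related genes were lower than higher: of 50 with counts, 11 rose, 25 fell and 14 did not pass. Thaumatin-like protein 1 (AGIS_Os10g004200) changed by -3.53 ± 0.35. Of the glutathione S-transferases, 26 had counts, of which 19 rose, 5 fell and 2 did not pass, and GSTF10 (AGIS_Os10g032780) was among the lower ones (-3.02 ± 0.36). Of the thiol redox proteins, 9 had counts, of which 1 rose, 7 fell and 1 did not pass, with glutaredoxin-C14 (AGIS_Os12g032200) at -2.94 ± 0.28. The plastid Cu/Zn superoxide dismutase stood at 59.3 ± 3.36 FPKM (-1.89 ± 0.15), and 4 genes of the ROS scavenging list fell and none rose. Among class III peroxidases, of 30 with counts, 1 rose, 25 fell and 4 did not pass, with peroxidase 1 (AGIS_Os05g036920) at -2.16 ± 0.30. A peroxidase 22.3 gene outside that list's pattern (AGIS_Os07g043560, chromosome 7, 28922096 to 28924026) rose from 1.07 ± 0.261 to 39.9 ± 3.54 FPKM, and of the 6 peroxidases outside the pattern 1 rose and 4 fell. In flavonoid synthesis, of 11 with counts, 7 rose, 2 fell and 2 did not pass, and an anthocyanidin glucosyltransferase (AGIS_Os01g045970) rose by 1.91 ± 0.19. In phenylpropanoid and lignin synthesis, of 27 with counts, 4 rose, 20 fell and 3 did not pass, although laccase-6 rose by 3.66 ± 0.18. Of the cytochrome P450 genes, 65 had counts, of which 36 rose, 21 fell and 8 did not pass. By Fisher's exact test the BH p for direction was 2.45e-05 for diterpenoid genes, 9.37e-05 for glutathione S-transferases, 9.37e-05 for cytochrome P450 and 0.00240 for class III peroxidases. With an absolute log2 change of at least 2, fewer members were left and the tests of glutathione S-transferases (range over alternatives 9.07e-05 to 0.900) and class III peroxidases (0.00216 to 0.205) did not pass. The tests of pathogenesis-related proteins (BH p = 0.954), thiol redox proteins (0.525) and phenylpropanoid genes (0.211) did not pass (Fisher's exact test). For flavonoid genes it was 0.0445 (Fisher's exact test, 7 higher). Without CK replicate 1, CK replicate 2, CdSeNP replicate 1 or CdSeNP replicate 2 it was 0.0601, 0.0551, 0.0528 and 0.0602, with a range over alternatives of 0.0467 to 0.123, highest with library totals. A minimum of 1 FPKM or an adjusted p under 0.01 also ended that call. The adjusted p of these genes was at most 1.86e-09 in the authors' deposited table (DESeq2), for GSTF10 with a log2 change of -3.02.

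Called genes of cell wall remodelling, of the cell cycle and of the ERF and DREB family were mostly lower in CdSeNP than in CK. In cell wall remodelling, of 44 with counts, 1 rose, 42 fell and 1 did not pass. Pectinesterase 1 (AGIS_Os01g017980) fell from 15.4 ± 3.98 to 3.73 ± 0.756 FPKM (-2.15 ± 0.26), and XTH24 changed by -2.17 ± 0.22. Of the cell cycle and chromatin genes, 59 had counts, of which 1 rose, 36 fell and 22 did not pass, with the histone H3.1 gene AGIS_Os05g031790 at -4.46 ± 0.63. PDF1 (AGIS_Os01g009060), protodermal factor 1, changed by -3.98 ± 1.09. Among auxin response genes, of 18 with counts, 4 rose, 12 fell and 2 did not pass, with IAA2 (AGIS_Os01g008110) at -1.63 ± 0.17 and SAUR71 (AGIS_Os06g041890) at 2.61 ± 0.33. All 19 ERF and DREB factors called were lower, with ERF109 at -4.80 ± 0.31, and FLZ14 changed by -4.66 ± 0.34. Among ABA, LEA and dehydrin proteins, all 15 with counts passed, 2 of them higher and 13 lower, with Rab16B (AGIS_Os11g022460) at -2.70 ± 0.29. Of the heat shock proteins, all 5 with counts passed, 1 of them higher and 4 lower, with the plastid HSP21 (AGIS_Os10g005600) at -2.57 ± 0.31. The direction of cell wall (BH p = 1.28e-05), cell cycle (BH p = 6.77e-05) and ERF and DREB genes (BH p = 0.00284) differed from that of other called genes (Fisher's exact test, 42, 36 and 19 members lower). The tests of auxin response (BH p = 0.926), ABA, LEA and dehydrin (0.244) and heat shock genes (0.926) did not pass (Fisher's exact test). With an absolute log2 change of at least 2, fewer members were left and the tests of cell wall (range over alternatives 5.69e-06 to 0.171) and ERF and DREB genes (0.00280 to 0.0595) did not pass. In the authors' deposited table (DESeq2) the largest adjusted p of these genes was 0.00122, for PDF1 with a log2 change of -3.98.

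The comparison of CdSeNP with Cd asked how adding SeNP altered leaves already exposed to Cd. Of all called genes, 8.64% were higher. Cell cycle genes were among those that fell most, and the metal-handling genes fell in part. Of the cell cycle and chromatin genes, 69 had counts, of which 0 rose, 66 fell and 3 did not pass. The histone H3.1 gene AGIS_Os05g031790 fell from 34.0 ± 18.2 to 0.311 ± 0.238 FPKM (-6.69 ± 0.59), a histone H2A.6 gene (AGIS_Os05g001350) changed by -4.95 ± 0.48 and PDF1 by -5.34 ± 1.07. Among markers of other tissues, 1 rose and 3 fell. The median over 5 of these markers was 1.38 ± 0.373 FPKM in Cd and 0.596 ± 0.166 in CdSeNP, while their summed FPKM overlapped (13.0 to 16.4 in Cd and 12.7 to 14.6 in CdSeNP). MT4C fell from 1067 ± 233 to 186 ± 63.1 FPKM (-2.45 ± 0.30), MT4B changed by -1.55 ± 0.31, YSL2 by -1.69 ± 0.19 and Nramp1 by -1.48 ± 0.20. Of the metallothioneins, 7 had counts, of which 1 rose, 4 fell and 2 did not pass, and without Cd replicate 1 none rose and 3 fell. Among metal transporters, of 11 with counts, 0 rose, 4 fell and 7 did not pass. In cell wall remodelling, 33 of 36 genes with counts fell and none rose. All 25 class III peroxidases called were lower, among them peroxidase 73 (AGIS_Os09g038670, -2.56 ± 0.39) and peroxidase 1 (-2.09 ± 0.36). Of the pathogenesis-related proteins, 51 had counts, of which 3 rose, 32 fell and 16 did not pass. Chitinase 2 (AGIS_Os05g028730) and chitinase 1 (AGIS_Os10g022490), which break down fungal walls, changed by -2.44 ± 0.36 and -2.03 ± 0.26, while PR1 rose by 1.58 ± 0.21. Of the glutathione S-transferases, 23 had counts, of which 0 rose, 7 fell and 16 did not pass, with GSTF10 at -2.17 ± 0.41. Of the auxin response genes, 27 had counts, of which 1 rose, 19 fell and 7 did not pass, and without Cd replicate 1 none rose and 12 fell. IAA30 (AGIS_Os12g037610) changed by -1.81 ± 0.30 and the water channel PIP2-6 (AGIS_Os04g013370) by -1.62 ± 0.36. Among ABC transporters, of 18 with counts, 1 rose, 11 fell and 6 did not pass. Without Cd replicate 1 those counts were 1 and 4, and without Cd replicate 3 or CdSeNP replicate 2 they were 1 and 6 (1 and 7 without CdSeNP replicate 1). In phenylpropanoid and lignin synthesis, of 26 with counts, 2 rose, 15 fell and 9 did not pass. Without Cd replicate 1 those counts were 1 and 8, and without Cd replicate 3 they were 2 and 9. Genes that rose included a beta-amylase (AGIS_Os07g031830, 2.42 ± 0.34), the peroxidase 22.3 gene AGIS_Os07g043560 (2.13 ± 0.21; 2 others outside the pattern fell), AARE (1.73 ± 0.16), SAG39 (1.73 ± 0.24) and a receptor-like kinase gene (AGIS_Os08g013480, 1.57 ± 0.19). Cytochrome P450 genes (9 higher, 13 lower) differed in direction from other called genes (Fisher's exact test, BH p = 3.29e-04). Cell cycle genes did so too (Fisher's exact test, BH p = 0.0270, 66 lower), but not without Cd replicate 1 (55 lower, 0.0530) or Cd replicate 2 (63 lower, 0.0561), nor with library totals or an absolute log2 change of at least 2 (range over alternatives 0.0244 to 0.936). Of the other lists in this paragraph none passed (Fisher's exact test, lowest BH p = 0.246, cell wall remodelling, with 0.339 for class III peroxidases and 1.00 for pathogenesis-related proteins). With only 8.64% of called genes higher, the test had little room for wholly lower lists of this size. For 33 cell wall genes lower and 0 higher, its p before adjustment was 0.108 (Fisher's exact test), so such outcomes decide little. The adjusted p of the genes named here was at most 6.05e-04 in the authors' deposited table (DESeq2), for PIP2-6 with a log2 change of -1.62.

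How far the Cd response went back toward CK was read from the genes called between Cd and CK. Of the 1038 genes higher with Cd, 282 (27.2%) were lower again in CdSeNP than in Cd, among them MT4C, YSL2, Nramp1 and histone H3.1 (AGIS_Os05g031790). Both comparisons use the Cd libraries. Independent lists would share 62.8 genes, and simulated libraries with CdSeNP equal to Cd shared a mean of 19.9 genes in this direction, scaled to the genes tested (6.22 without any group difference). The 19.9 was scaled up from 1.6 in the 1773 genes simulated. Those genes were drawn independently, so an overlap from a shift of many genes in 1 Cd library is not measured by it. In CdSeNP, 165 of the 282 were not called against CK, 94 were called lower than CK and 23 stayed higher. A further 533 of the 1038 were higher than CK in CdSeNP as well and not called between CdSeNP and Cd, and 18, among them PR1, rose further. Another 205 were called neither between CdSeNP and Cd nor between CdSeNP and CK. Of the 430 genes lower with Cd, 28 (6.51%) were higher again with SeNP, and 15 with library totals, against 2.46 for independent lists, 9.95 in those simulated libraries and 16.2 without any group difference. Of the rest, 234 were lower than CK in CdSeNP and not called between CdSeNP and Cd, 156 were called in neither comparison, and 12 fell further. The 282 genes fell to 138 without Cd replicate 1 and to 174 without CK replicate 1, and the total of 310 to 159 and 201.

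**Figure D3:**
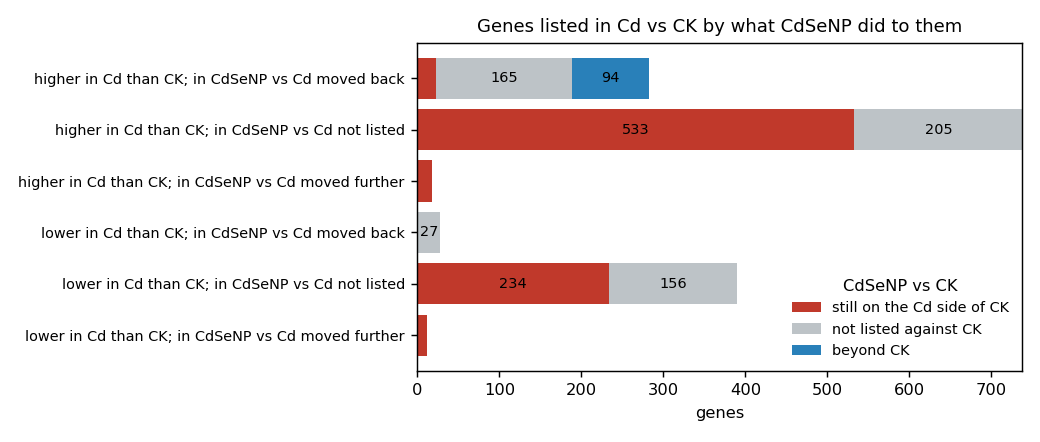
Number of genes called between Cd and CK (horizontal bars, higher and lower with Cd), divided by their call between CdSeNP and Cd and by their call between CdSeNP and CK. Of 1038 genes higher with Cd, 282 were lower again with SeNP, and 94 of these were lower than CK.

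The comparison of CdSeNP with SeNP asked whether Cd acted in the same way when SeNP was present. Metal-handling genes were again among those that rose most. MT4C rose from 6.94 ± 1.92 to 186 ± 63.1 FPKM (4.68 ± 0.33), MT4B by 5.25 ± 0.45 and YSL2 by 2.23 ± 0.19. Of the iron homeostasis genes, 10 had counts, of which 7 rose, 1 fell and 2 did not pass, with IRO2 at 2.23 ± 0.21. A gene described as DMAS1, an enzyme of mugineic acid synthesis (AGIS_Os04g032400), rose by 2.21 ± 0.16. Among metal transporters, all 11 with counts passed, 9 of them higher and 2 lower, with ZIP2 at 51.3 ± 2.83 FPKM in CdSeNP and 10.7 ± 1.89 in SeNP, the copper transporter COPT1 (AGIS_Os01g048930) at 2.03 ± 0.15 and VIT2 at -2.58 ± 0.26. All 6 metallothioneins called were higher. In diterpenoid phytoalexin synthesis, of 25 with counts, 21 rose, 1 fell and 3 did not pass. The gene described as an ent-cassadiene hydroxylase (AGIS_Os04g023660) rose by 3.75 ± 0.20. Of the WRKY factors, 28 had counts, of which 20 rose, 1 fell and 7 did not pass. WRKY45-1 rose by 2.21 ± 0.19 and WRKY24 (AGIS_Os01g053440) by 1.65 ± 0.18. Of the NAC factors, 19 had counts, of which 11 rose, 3 fell and 5 did not pass, and without CdSeNP replicate 2 the counts were 8 and 1. A gene described as NAP, a factor of leaf senescence (AGIS_Os07g043940), rose by 1.37 ± 0.12. PR1 rose by 3.28 ± 0.22, the peroxidase 22.3 gene AGIS_Os07g043560 by 4.35 ± 0.20 (2 others outside the pattern fell), GSTU6 (AGIS_Os10g031540) by 2.28 ± 0.30, the ammonium transporter AMT3 (AGIS_Os03g054330) by 1.86 ± 0.18, and a SCARECROW-like gene (AGIS_Os07g044270) by 4.07 ± 0.39. In cell wall remodelling, of 40 with counts, 1 rose, 31 fell and 8 did not pass (14 fell without SeNP replicate 2 and 16 without CdSeNP replicate 2), with pectinesterase 1 at -1.67 ± 0.30. Beta-xylosidase 7 (AGIS_Os11g015870) changed by -2.57 ± 0.25, glutaredoxin-C14 by -2.39 ± 0.25 and the plastid Cu/Zn superoxide dismutase by -1.81 ± 0.12. Among class III peroxidases, of 27 with counts, 3 rose, 17 fell and 7 did not pass. Of the auxin response genes, 24 had counts, of which 6 rose, 15 fell and 3 did not pass, and without SeNP replicate 2 the counts were 6 and 7. Of the cell cycle genes, 68 had counts, of which 1 rose, 8 fell and 59 did not pass, and without CdSeNP replicate 2 the counts were 1 and 2 (1 and 5 without SeNP replicate 2 or CdSeNP replicate 1). Of the thiol redox proteins, 5 fell and none rose, and 3 fell without CdSeNP replicate 2. In the authors' deposited table (DESeq2) the largest adjusted p of these genes was 5.25e-11, for pectinesterase 1 with a log2 change of -1.68.

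By direction within the called genes (Fisher's exact test), the lists set apart in CdSeNP against SeNP were cell wall remodelling (BH p = 1.38e-06, 31 lower), cytochrome P450 (2.45e-05, 38 higher), diterpenoid synthesis (6.77e-05, 21 higher) and WRKY factors (9.57e-05, 20 higher). With an absolute log2 change of at least 2, fewer members were left and the tests of cytochrome P450 (range over alternatives 1.57e-05 to 0.197) and diterpenoid genes (1.74e-05 to 0.280) did not pass. The metallothionein, metal transporter, iron, NAC, auxin, cell cycle and thiol redox lists did not pass (Fisher's exact test, lowest BH p = 0.0629, metallothioneins). For class III peroxidases the BH p was 0.0131 (17 lower). Without SeNP replicate 2 it was 0.101 (8 lower), without CdSeNP replicate 2 0.0693 (9 lower) and without CdSeNP replicate 3 0.0725 (12 lower), with a range of 0.0132 to 0.101. Glutathione S-transferases had 18 higher and 4 lower (Fisher's exact test, BH p = 0.0131). That test did not pass when any of the 3 SeNP or 3 CdSeNP replicates was left out (lowest 0.0648 and highest 0.375), nor with library totals, an adjusted p under 0.01 or an absolute log2 change of at least 2, and over the alternatives run it ranged from 0.0218 to 1.00. The Cd effect with SeNP shared no library with the Cd effect without it. Of the 1038 genes higher with Cd alone, 564 were also higher when Cd was added to SeNP, against 46.3 for independent lists, and 7 were lower. Of the 430 lower genes, 56 were also lower (34 with library totals), against 19.3, and 2 were higher. IRO2, YSL2, MT4C, PR1 and GSTU6 (AGIS_Os10g031540) were among the genes higher in both, and the plastid Cu/Zn superoxide dismutase and VIT2 among those lower in both.

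The comparison of SeNP with Cd set the single additions against each other. Metallothionein genes were among those with the largest falls in SeNP against Cd. MT4C stood at 6.94 ± 1.92 FPKM in SeNP and 1067 ± 233 in Cd (-7.12 ± 0.26), and MT4B, YSL2, IRO2 and ZIP1 changed by -6.79 ± 0.36, -3.91 ± 0.20, -3.58 ± 0.24 and -3.35 ± 0.27. VIT2 rose by 2.66 ± 0.29. Of the pathogenesis-related proteins, 59 had counts, of which 1 rose, 45 fell and 13 did not pass, with wheatwin-1 (AGIS_Os11g032460) at -2.46 ± 0.21 and a glucanase gene (AGIS_Os01g062670) at -2.33 ± 0.19. All 25 WRKY factors called were lower, with WRKY45-1 (AGIS_Os03g019350) at -2.21 ± 0.26 and WRKY62 (AGIS_Os09g031610) at -2.11 ± 0.25. Of the NAC factors, 20 had counts, of which 1 rose, 15 fell and 4 did not pass, with NAP at -2.01 ± 0.17. In jasmonate synthesis and signalling, of 16 with counts, 2 rose, 11 fell and 3 did not pass (7 fell without Cd replicate 2), with the lipoxygenase LOX7 (AGIS_Os08g036940) at -2.11 ± 0.26. All 19 diterpenoid genes called were lower. Of the glutathione S-transferases, 26 had counts, of which 1 rose, 20 fell and 5 did not pass, with GSTU6 (AGIS_Os10g031540) at -2.60 ± 0.26. Among class III peroxidases, of 26 with counts, 1 rose, 12 fell and 13 did not pass, with peroxidase 47 at -2.49 ± 0.20. Of the cell cycle genes, 67 had counts, of which 1 rose, 65 fell and 1 did not pass, with histone H3.1 (AGIS_Os05g031790) at -5.32 ± 0.51. In cell wall remodelling, of 27 with counts, 2 rose, 7 fell and 18 did not pass, and without Cd replicate 1 the counts were 1 and 3. The asparagine synthetase ASN1 (AGIS_Os03g015940) changed by -2.59 ± 0.17. A beta-amylase gene (AGIS_Os07g031830) rose by 3.15 ± 0.28, RADIALIS-like 3 (AGIS_Os06g025070) by 2.30 ± 0.24 and the plastid Cu/Zn superoxide dismutase by 1.43 ± 0.17. By Fisher's exact test the BH p for direction was 0.0102 for pathogenesis-related proteins (45 lower) and 2.88e-04 for cell cycle genes (65 lower). With an absolute log2 change of at least 2 neither passed (ranges over alternatives 0.00292 to 1.00 and 1.02e-04 to 0.185). For WRKY factors it was 0.0403 (25 lower), and it passed under none of the 11 alternatives run for it, which were 3 stricter thresholds, library totals, the edgeR refit and leaving out each of the 6 libraries (lowest 0.0623 and highest 0.0970 without a library, range over the 11 0.0621 to 1.00). No other list in this paragraph passed (Fisher's exact test, lowest BH p = 0.124, diterpenoid genes). The adjusted p of the genes named here was at most 1.61e-12 in the authors' deposited table (DESeq2), for histone H3.1 with a log2 change of -5.32.

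**Figure D4:**
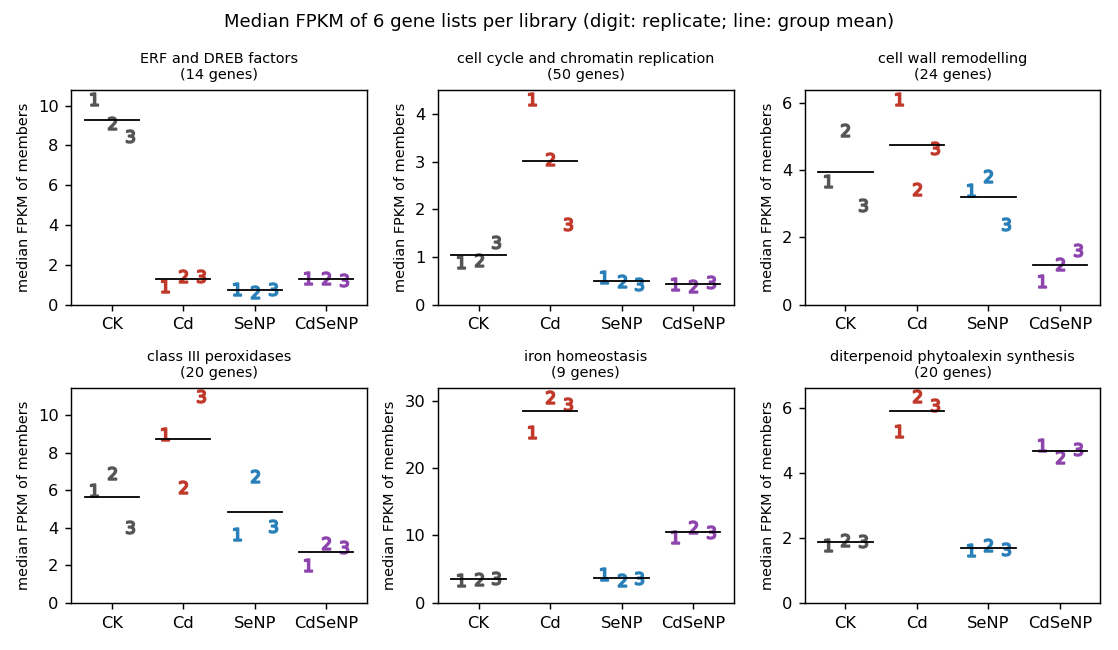
Median FPKM (vertical axes) of the members of 6 gene lists in each library of the 4 groups (digits, replicate numbers; lines, group means). ERF and DREB factors were lower than CK in all 3 treatments, and cell cycle genes spread from 1.68 to 4.32 in Cd.

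The SeNP effect was compared between leaves without and with Cd, in comparisons that shared no library. Of the 77 genes higher with SeNP alone, 19 were also higher when SeNP was added to Cd, against 0.451 for independent lists, and 8 were lower. Of the 458 lower genes, 112 were also lower, against 28.4. Without CK replicate 1 the 112 fell to 70 and the total of 131 to 85. AARE and SAG39 were higher in both, and the histone H3.1 gene AGIS_Os05g031790 was lower in both. All 3 treatments had genes in common against CK. There, 130 genes were lower in Cd, SeNP and CdSeNP, 14 of them ERF and DREB factors such as ERF109 and DREB1B, and 27 were higher. Those comparisons share the CK libraries, and simulated libraries with SeNP equal to CK gave means of 6.07 lower and 1.21 higher genes, scaled to the genes tested. They were scaled up from means of 0.5 and 0.1 over 10 runs in the 1773 genes simulated, so they are rough. These simulated libraries, too, held no shift shared by many genes. Of the 130 genes, 108 were not called between any pair of treatments. The ERF and DREB factors had a median of 9.31 ± 0.942 FPKM in CK over 14 genes (SD, n = 3). Their median was 1.28 ± 0.298 in Cd, 0.741 in SeNP and 1.30 ± 0.0428 in CdSeNP.

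Whether the Cd response itself changed with SeNP was tested as an interaction in the 1773 genes with counts in all 12 libraries (edgeR). It passed for 845 genes: in 241 the Cd response was more positive with SeNP and in 604 it was more negative. Without Cd replicate 1, 546 passed, 344 of them more negative, and without SeNP replicate 2, 370 were more negative. The interaction was positive for ERF109 (4.36 on the log2 scale) and DREB1B (4.02), which were low in SeNP with or without Cd. It was negative for IRO2 (-4.30), which Cd raised less when SeNP was present, and for MT4C (-1.19), whose call was lost without CK replicate 1 (adjusted p in edgeR 0.0549), Cd replicate 1 (0.0605) or SeNP replicate 2 (0.0716; range over alternatives 0.0129 to 0.0716). IRO2 stood at 2.15 ± 0.515 FPKM in SeNP and 10.5 ± 0.744 in CdSeNP, against 0.269 ± 0.0225 in CK and 28.5 ± 2.71 in Cd. Of 50 cell cycle genes tested, 37 had a more negative Cd response with SeNP, and 19 without Cd replicate 1 or 22 without SeNP replicate 1.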

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

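All tests of explanations in this part were chosen after the result was seen, and the interaction test was planned. The results listed are differences in the Cd response between leaves with and without SeNP, found by the edgeR interaction test (BH).

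The interaction passed for 845 of 1773 genes, with a more positive Cd response under SeNP in 241 and a more negative one in 604. In 100 splits of the libraries, none of the other splits reached the real count of 845 (highest 563), so 1 of 100 was as large. The tested genes were listed because the same groups differed, so this decides nothing about chance. Single genes with a more positive Cd response under SeNP included ERF109 (AGIS_Os08g034130, 4.36 on the log2 scale), an ALP1-like gene (AGIS_Os01g007870, 4.23) and DREB1B (AGIS_Os09g039870, 4.02). DREB1G (AGIS_Os02g040840, 3.86), CYP94C1 (AGIS_Os11g004370, 3.01) and DREB1A (AGIS_Os09g039890, 2.67) were others. CYP94C1 was lower than CK with Cd alone and with SeNP alone. A more negative response was found for IRO2 (AGIS_Os01g063630, -4.30), MT4C (AGIS_Os12g035090, -1.19, lost without CK replicate 1, Cd replicate 1 or SeNP replicate 2), and 3 genes described as trehalose-phosphate synthase 10 (AGIS_Os05g002810, -4.60; AGIS_Os12g028600, -4.86, with only 2 to 3 counts per CK library; and the third locus, outside the AGIS annotation, -4.21). Nramp1 (AGIS_Os07g013740, -3.38) and YSL2 (AGIS_Os02g038710, -2.90) had a more negative response as well. Among lists, a more positive response was found in 13 of 14 ERF and DREB factors, 12 of 24 WRKY factors and 4 of 8 jasmonate genes. For ERF and DREB factors this was mostly the absence of a fall, not a rise. In CdSeNP against SeNP, of 19 with counts, 1 rose, 1 fell and 17 did not pass. Their median over 14 genes was already 0.741 FPKM in SeNP and was 1.30 in CdSeNP, against 9.31 in CK and 1.28 in Cd. A more negative response was found in 5 of 9 iron homeostasis genes. It was also found in 37 of 50 cell cycle genes (19 without Cd replicate 1, 22 without SeNP replicate 1). In cell wall remodelling it was found in 17 of 24 genes (7 without Cd replicate 1 or SeNP replicate 2, 9 without CK replicate 3 or CdSeNP replicate 1, 10 without CK replicate 1, 11 without CdSeNP replicate 2). Among class III peroxidases it was found in 11 of 20 (4 without Cd replicate 1 or SeNP replicate 2, 6 without CK replicate 3 or CdSeNP replicate 1, 7 without CK replicate 1). Among auxin response genes it was found in 8 of 15 (5 without CK replicate 3, Cd replicate 1 or SeNP replicate 2).

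The positive interactions of ERF and DREB factors go with a wider pattern, 130 genes lower than CK in Cd, SeNP and CdSeNP alike. One CK library as the cause is argued against, since leaving out a CK library kept at least 364 of the 390 calls. The authors' scaling as the cause is argued against too, since scaling by library totals kept 357 of 390. CK leaves handled or sampled at another moment than treated leaves remain possible, because only 22 of the 130 genes were called between any pair of treatments and the design ties such a difference to the control group. A shared response of leaves to Cd and to selenium stays open beside it and was not tested, since no other kind of treatment was sequenced.

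Cell cycle genes were higher in Cd than in CK and lower in CdSeNP than in Cd. The rise leans on single libraries, as 18 of 48 calls were kept without Cd replicate 1 (39 without Cd replicate 2, 48 without Cd replicate 3) and 29 without CK replicate 1 or CK replicate 2, so a difference of single leaves and a Cd effect cannot be told apart there, with 3 libraries per group. The fall with SeNP is less dependent on it, as at least 55 of 66 calls were kept whichever Cd library was left out. Reads shared between histone copies are argued against as the whole cause, since 27 of the 48 higher members were not histones. More young dividing tissue in the sampled Cd leaves may account for the rise and is left open. Of the markers of root, meristem or flower, 4 were higher and 1 lower in Cd than in CK. The most abundant was a gene described as GRF12 (AGIS_Os10g024970, 9.43 ± 1.73 FPKM in Cd). These 5 are too few to decide, and 2 of them were at 1 FPKM or more in CK leaves too. In CdSeNP against Cd, 1 marker was higher and 3 lower, the direction of the cell cycle genes. SeNP gives no clear direction for the 5 markers with counts in all 12 libraries, which need not be the called ones. Their median was 1.47 ± 0.146 FPKM in SeNP, 1.38 ± 0.373 in Cd and 0.608 ± 0.0434 in CK. Their summed FPKM was 7.50 to 7.85 in SeNP, 13.0 to 16.4 in Cd and 6.19 to 7.72 in CK. In SeNP against CK, 1 marker was higher, 0 lower and 5 did not pass. In SeNP, 23 cell cycle genes were lower than in CK and 0 higher.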

How the results depend on the processing

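Added after the data were seen were edgeR refits and library totals throughout, DESeq2 refits of overlaps and the interaction, and leaving out replicates for list tests. Library totals left 1308, 460, 2199, 1383, 1717 and 1712 genes in the order of comparisons below. Of 454 pairs of named gene and comparison, with 4540 alternatives, 4445 kept their call, 95 lost it and 0 reversed. An absolute log2 change of at least 2 left 225 genes for Cd vs CK, 123 for SeNP vs CK, 530 for CdSeNP vs CK, 462 for CdSeNP vs Cd, 266 for CdSeNP vs SeNP and 411 for SeNP vs Cd, since fewer genes can pass. It left 77 genes for the Cd effect shared with and without SeNP, 20 for the SeNP effect, 29 for the return toward control, and 5 of 25 lists. Fitting all 12 libraries, which covers fewer genes, gave 998, 346, 1434, 898, 1226 and 1074 in that order. Leaving out 1 replicate gave 1221 to 1397 genes for Cd vs CK, 407 to 470 for SeNP vs CK, 2119 to 2344 for CdSeNP vs CK, 1010 to 1353 for CdSeNP vs Cd, 1426 to 1782 for CdSeNP vs SeNP and 1552 to 1707 for SeNP vs Cd. It gave 535 to 605 for the shared Cd effect, 85 (without CK replicate 1) to 106 for the SeNP effect, 159 (without Cd replicate 1) to 297 for the return, with 201 without CK replicate 1, and 546 (without Cd replicate 1) to 917 for the interaction; the cause was not tested. With replicate number as a block the counts were 1425, 493, 2287, 1217, 1693 and 1762 in the order above, 597, 98 and 274 for the overlaps and 618 for the interaction. No label pairs libraries of equal number. The correlations gave no sign of such pairing, as 4 of 18 same-number and 18 of 36 other-number correlations lay over 0.1. With 3 libraries per group they cannot exclude it. TMM scaling, pseudocounts and filters on all expressed genes were not run. The splits of 6 libraries are 10, too few for a share under 0.05: 1 of 10 was as large each time, with real and highest other counts of 1449 and 28 for Cd vs CK, 523 and 24 for SeNP vs CK, 2456 and 2 for CdSeNP vs CK, 1401 and 5 for CdSeNP vs Cd, 1865 and 15 for CdSeNP vs SeNP, and 1828 and 7 for SeNP vs Cd. The genes used were listed because groups differed, so the real split was favoured and these counts decide nothing about chance. At this depth, simulated changes of 1 on the log2 scale were recovered by p-value and direction in 59% (CdSeNP vs Cd) to 91% (CdSeNP vs CK) of genes. The minimum absolute log2 change was not applied there, so the share that would be called by both thresholds was not measured.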

Other observations

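The test of copper proteins in this part was chosen after the result was seen, and the lists were planned. The lists of photosynthesis and of cytosolic ribosomal proteins matched few called genes by their words, and no test against expressed members was run. No called gene matched the chlorophyll synthesis list. Carbon fixation had 1 gene lower in Cd and 1 in CdSeNP against CK. Photosystems and light harvesting had 2 genes, both higher in SeNP than in Cd. Cytosolic ribosomal proteins had at most 1 gene higher and 1 lower in a comparison, and clock genes at most 1 higher and 2 lower. Sulfur and selenium assimilation had 1 gene lower with Cd and 1 lower with SeNP against CK. In CdSeNP against CK, all 6 with counts passed, 2 of them higher and 4 lower; adenylyl-sulfate kinase 3 (AGIS_Os11g035930) changed by -1.25 ± 0.26 there.

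Of all called genes, 70.7% were higher in Cd than in CK. In nitrogen uptake and assimilation, of 6 with counts, 3 rose, 1 fell and 2 did not pass for Cd against CK. The ammonium transporter AMT3 (AGIS_Os03g054330) stood at 6.79 ± 0.239 FPKM in CK, 31.0 ± 5.42 in Cd, 6.92 ± 1.23 in SeNP and 26.1 ± 1.18 in CdSeNP (SD, n = 3). Of the senescence genes, 8 had counts, of which 5 rose, 1 fell and 2 did not pass for Cd against CK (3 rose without CK replicate 1), and 6 were lower in SeNP than in Cd. In flavonoid synthesis, of 13 with counts, 8 rose, 2 fell and 3 did not pass for Cd against CK. Of the phosphate starvation genes, 7 had counts, of which 1 rose, 5 fell and 1 did not pass for CdSeNP against CK, with the phosphate transporter PHO1-1 (AGIS_Os01g001000) at -1.34 ± 0.19. Of the aquaporins, 5 had counts, of which 0 rose, 4 fell and 1 did not pass for CdSeNP against CK. Markers of other tissues had 3 higher and 5 lower in SeNP than in Cd. For these comparisons the nitrogen and aquaporin lists had too few called members to test, and none of the others passed the test of direction (Fisher's exact test, lowest BH p = 0.342, markers of other tissues).

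The 3 listed genes of Cu/Zn superoxide dismutase and its chaperone CCS were lower with Cd than in CK, while the copper transporters COPT1 and COPT5.2, named after their values were seen, were higher. For superoxide dismutase 2 (AGIS_Os07g042510) the call was lost with library totals. A copper-saving response, in which leaves cut back copper proteins, may account for this. Other copper proteins, such as laccases and plastocyanin-like proteins, would then be lower as well. Of these, 8 were higher and 5 lower in Cd than in CK (Fisher's exact test, p = 0.541, BH p over 3 comparisons 0.812). In CdSeNP 6 were higher and 29 lower than in CK (Fisher's exact test, p = 0.0313, BH p = 0.0940), and in SeNP 1 was higher and 7 lower (p = 1). The tests leave the explanation open, since the other copper proteins went both ways in Cd.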
